A study of Mus musculus with 28 samples.

How the data were processed

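Splenic dendritic cells of C57Bl/6 mice aged 6 to 12 weeks were sorted by flow cytometry from untreated animals and profiled by bulk RNA-seq, per the labels. Conventional type 1 dendritic cells (cDC1, CD24+), conventional type 2 dendritic cells (cDC2, CD172a+) and plasmacytoid dendritic cells (pDC) came from Irf8fl/fl mice, which carry a loxP-flanked Irf8 gene and no Cre and are called WT in the labels. A further pDC group came from Irf8fl/fl Itgax-cre mice, in which the Cre recombinase is driven by regulatory sequence of Itgax (the CD11c gene), and is called pDC_TG here. There were 28 libraries in 4 groups: 8 each of cDC1_WT, cDC2_WT and pDC_WT and 4 of pDC_TG. The design text speaks of 4 replicates per sample, so fits with WT replicates 1 to 4 or 5 to 8 alone were among the alternatives.

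Per the labels' protocols, spleens were digested for 30 min at 37 degrees, 4 ng of total RNA per sample was amplified with the SMART-Seq v4 kit, 1 ng of cDNA was sheared to 300 bp, and libraries with 250 bp inserts were made with 15 PCR cycles and sequenced as single 75 bp reads on 2 NextSeq500 flow cells. Which library ran on which flow cell was not given in the sources used here, so a flow cell term was not fitted. The protocol does not mark strand, and PCR copies cannot be told from molecules. The floors cover counting error only, whereas the standard errors of the fit include the spread between libraries. Per the submitters' processing notes, FastQC 0.11.4, Trimmomatic 0.35, TopHat2 2.1.0 and SAMtools 0.1.18 were used with mouse genome build mm10; the counting tool and the annotation were not given in the sources used here. The authors deposited whole-number read counts per gene symbol, not normalized, for 24421 genes in each library, with 5 summary lines that were left out of library sizes and tests. Reads outside any gene made up 8.23% to 18.7% of each library's gene, no-feature and ambiguous counts, and ambiguous reads 1.04% to 1.57%.

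Gene counts per library averaged 23944567 ± 4365620 in pDC_WT (SD, n = 8), 25644201 ± 2876315 in pDC_TG (n = 4), 26144120 ± 1971816 in cDC1_WT (n = 8) and 24703822 ± 3007200 in cDC2_WT (n = 8). A floor of 3 counts over a group corresponded to 0.0146 CPM in pDC_WT, 0.0263 in pDC_TG, 0.0158 in cDC1_WT and 0.0156 in cDC2_WT. A gene without a count in every library of a group was compared by its level over that floor, written as at least N-fold, and a gene with 1 to 3 counts in a group is given by its levels alone. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom was 33.6 over genes with at least 20 counts. Transcripts of Xist and Ddx3y placed female mice at odd and male mice at even replicate numbers in every group, so sex was balanced between the groups.

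Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15), a robust quasi-likelihood fit of all 28 libraries together and two-sided quasi-likelihood tests for 6 comparisons. Of the genes, 13159 passed the filter, and Benjamini-Hochberg adjusted p below 0.05 over these genes was the threshold. Levels are TMM-scaled CPM (the unit of the cpm function of edgeR), computed here from the counts the authors deposited, and log2 fold changes (log2FC) come with the standard error (SE) of the fit. Irf8 was also tested by an exact permutation of its log2 CPM. Adjusted p-values of the main fit rest on an estimate of spread per gene shared by all 4 groups, not on pDC libraries alone. Same-numbered WT libraries count there as independent. A fit of the pDC libraries alone takes the spread from those libraries, and some calls differ between the fits.

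The comparisons, the lists of 24 gene groups, the rule for named genes and the alternatives were fixed before the data were examined. Named genes of pDC_TG versus pDC_WT are Irf8, the 10 largest rises and the 10 largest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between the libraries of both groups, and up to 4 members of each list with the smallest adjusted p. The 3 comparisons between WT groups name 5 rises, 5 falls and up to 3 members of each of the 4 identity lists, and those of pDC_TG with each cDC group name 5 rises and 5 falls. Predicted genes, antigen receptor segments and members of the other-cell lists were skipped among the largest changes. Other list members given with values were chosen after their values were seen. A few genes that these rules name are not reported here. The lists cover pDC identity, cDC1 identity, cDC2 identity, shared conventional DC, nucleic acid sensing and type I interferon induction, interferon-stimulated genes, MHC class II presentation, MHC class I and cross-presentation, costimulation and T cell priming, dendritic cell transcription factors, apoptosis regulators, cell cycle, migration and adhesion receptors, endoplasmic reticulum folding and secretion, C-type lectins and phagocytic receptors, and dissociation and immediate early genes. Markers of B cells, plasma cells, T cells, NK cells, monocytes and macrophages, neutrophils, and erythroid cells and platelets, and sex-linked genes, were included for other cells and for sample identity. Of 438 list entries, 428 were in the files and 411 were tested.

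List members past the threshold were counted over all genes tested and adjusted over the list alone. Each list was tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the lists of a comparison. Of the 12 lists that camera called in pDC_TG versus pDC_WT, the calls of 4 held with an estimated correlation. These were interferon-stimulated genes, MHC class I and cross-presentation, apoptosis regulators and endoplasmic reticulum folding. Subset signatures were defined from odd-numbered pDC_WT and all cDC libraries (past the threshold and at least 4-fold), and pDC_TG was then tested against even-numbered pDC_WT, so that no control library served both steps. Correlations across genes used genes with a mean of at least 1 CPM, and 100 simulations of unchanged groups against the same controls gave a reference value. The simulated genes varied independently of each other, and their changes were plain log2 ratios of mean CPM without TMM scaling. The reference therefore leaves out chance correlation from genes that vary together.

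The procedures were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For pDC_TG versus pDC_WT, run on 12754 genes, 29.9% of 67 genes changed 1.5-fold, 47.8% of 67 changed 2-fold and 63.6% of 66 changed 4-fold were called, and 5.05% of the calls were false. In the signature step, run on 11285 genes, 126 tested pDC signature genes were lowered 4-fold and 77 signature genes were called lower. With 119 lowered 2-fold, on 11268 genes, 37 were called lower, and with no change 1 was. How many of these calls fell on the changed genes was not counted. A first version of this simulation, with a 2-fold lowering and the spread of all groups, recovered few of the changed genes; the spread was then taken from the pDC libraries and the fold raised to 4, and the 2-fold lowering was run again with that spread.

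Alternatives were DESeq2 size factors, upper-quartile scaling, total counts alone, no filter, a stricter filter (5 CPM in at least 4 libraries), the DESeq2 1.42.0 Wald test, limma-voom, fits of only the groups compared, WT replicates 1 to 4 or 5 to 8 alone, each library left out, a replicate block and a test against a 1.5-fold change. The source labels number the mice alike in the 3 WT populations, and on that ground alone the WT numbers were taken as pairs; no label states that equal numbers are 1 animal. Deviations from the group means of same-numbered WT libraries correlated with a mean of 0.164 (cDC1 with cDC2), 0.171 (cDC1 with pDC) and 0.181 (cDC2 with pDC). They were over 0.1 in 7, 7 and 6 of 8 pairs. Different numbers gave means of -0.023, -0.024 and -0.026. Deviations from a group mean cancel out over the group, so these negative means follow from the positive ones and are not a separate reference. The best match of a library was its own number in 8, 6 and 6 of 8 cases, so same-numbered WT libraries varied together. Same-numbered libraries also share sex, and the part of sex in this was not separated. The main fits held no term for the pair. A pDC_TG library shares only a number with a WT library, since the genotypes differ.

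Gene positions are 1-based and come from the GENCODE annotation of GRCm38, the assembly of build mm10. Of 24421 symbols, 24001 matched an annotated gene, 23334 by symbol and 667 by an older name. Of 161 named genes, 160 had a position, and 18 shared over 10% of their exonic bases with another annotated gene. Beside those stated with their results, these were Rab43 (75.4%), Snx22 (28.5%), P3h2 (28.4%), Ube2c (22.8%), Bid (17.7%), Tnfsf9 (14.9%), Irf5 (14.1%), Mcm7 (12.6%), Ccna2 (12.5%), Txndc5 (11.9%), Cd7 (10.8%) and Cox6a2 (10.3%) among the genes discussed, and their counts are uncertain to that extent. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.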

Results

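Gene expression was measured by bulk RNA-seq in dendritic cells (DCs) sorted from mouse spleen, in 8 libraries of cDC1 (cDC1_WT), 8 of cDC2 (cDC2_WT) and 8 of pDC (pDC_WT) from Irf8fl/fl mice, and in 4 libraries of pDC from Irf8fl/fl Itgax-cre mice (pDC_TG). cDC1 are specialised in presenting antigen to CD8 T cells, cDC2 in presenting it to CD4 T cells, and pDC in making type I interferon. The labels number separate mice, so the spread within a group includes that between mice. It can also include differences in handling between libraries, which could not be separated here. Gene counts per library ran from 17299285 to 30787679 in pDC_WT, 22805201 to 28725550 in pDC_TG, 23592099 to 30152305 in cDC1_WT and 20696141 to 29351715 in cDC2_WT, and 12039 to 13344 genes had a count in a library. The study addresses the role of the transcription factor IRF8 in the survival and function of terminally differentiated DCs. Values below are mean CPM ± SD, with n = 4 for pDC_TG and n = 8 for each WT group, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Positions are on GRCm38 (mm10), and all genes with a position given are annotated as protein coding.

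Irf8 (chromosome 8, 120736358 to 120756694), which encodes a transcription factor needed for the development of cDC1 and for the function of pDC, was at 6145 ± 459 CPM in pDC_WT and 1461 ± 257 CPM in pDC_TG, or 23.8% of the pDC_WT level. The libraries did not overlap, with a range of 5379 to 6537 CPM in pDC_WT and of 1166 to 1787 CPM in pDC_TG. The log2 fold change (log2FC) was -2.07 (SE 0.12, adjusted p = 4.43e-13). An exact two-sided permutation test over 495 splits gave p = 0.00202, the smallest it can give. Among the other WT populations, cDC1_WT held 4024 ± 169 CPM, 65.5% of the pDC_WT level, and cDC2_WT 72.3 ± 14.6 CPM, or 1.18%. The counts are per gene and include exons outside a deleted part, so they do not give the share of cells with a deleted allele.

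**Figure D1:**
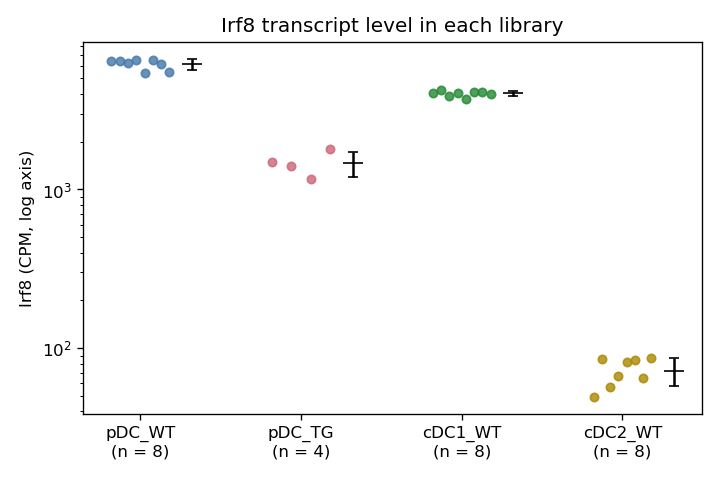
Irf8 level in each library (CPM, log axis) by group, with the group mean and SD. The 4 pDC_TG libraries lie between 1166 and 1787 CPM, below all 8 pDC_WT libraries (5379 to 6537 CPM), and cDC2_WT lies lowest at 72.3 ± 14.6 CPM.

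The comparison of pDC_TG with pDC_WT asks what changes in pDC when the Cre is present on the loxP-flanked background. Genes that are low in control pDC were among the largest rises. Rtp4, an interferon-inducible chaperone gene (chromosome 16, 23520291 to 23614222), rose from 1.57 ± 1.13 to 150 ± 28.3 CPM (log2FC 6.59, SE 0.47, adjusted p = 4e-11). Plcb1, which encodes a phospholipase C (chromosome 2, 134786067 to 135475258), rose from 0.0380 ± 0.0704 to 15.7 ± 5.09 CPM (log2FC 8.40, SE 0.84, adjusted p = 1.04e-08). Itgam, which encodes the integrin CD11b (chromosome 7, 128062640 to 128118491), rose from 0.401 ± 0.664 to 31.9 ± 8.49 CPM (log2FC 6.23, SE 0.70, adjusted p = 3.29e-08). The sulfotransferase gene Chst2 rose from 0.731 ± 1.14 to 71.9 ± 18.1 CPM (log2FC 6.57, SE 0.76). Among the largest falls, Clec9a, a receptor for dead cells (chromosome 6, 129408862 to 129424763), dropped from 91.6 ± 19.9 to 6.60 ± 2.72 CPM (log2FC -3.80, SE 0.21, adjusted p = 3.2e-12). The lectin gene Clec10a fell from 251 ± 36.7 to 35.2 ± 12.1 CPM (log2FC -2.84, SE 0.25), the nucleotide receptor gene P2ry6 from 70.9 ± 12.1 to 8.10 ± 4.20 CPM (log2FC -3.13, SE 0.20) and the growth factor receptor gene Egfr from 37.2 ± 9.64 to 4.96 ± 1.44 CPM (log2FC -2.90, SE 0.34).

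The other largest rises were Smoc1 (log2FC 7.04), Pard3b (6.19), Gpr25 (4.97), Tmem121 (4.82), Ifit3b (4.82) and Slc9a2 (4.76). The other largest falls were Col17a1 (log2FC -3.84), Slc22a23 (-3.43), Slc52a3 (-3.12), Itsn1 (-2.91), Rad51b (-2.89) and Cd209e (-2.87). Tmem121 lost its call with WT replicates 1 to 4 alone (adjusted p = 0.0538), with replicates 5 to 8 alone (0.0586) and in the DESeq2 Wald test (0.105). Slc22a23 was at 0 CPM in the pDC_TG libraries of female mice and at 3.91 CPM in those of male mice. Itgam, Gpr25 and Rtp4 share 68.7%, 41.6% and 13.9% of their exonic bases with another annotated gene, and since the reads carry no strand, their counts are uncertain to that extent. In all, 1016 genes were higher and 927 lower in pDC_TG among 13159 tested, of which 511 and 306 changed at least 2-fold. Against a 1.5-fold change rather than none, 337 genes were higher and 194 lower. A fit of the pDC libraries alone called 828 higher and 968 lower (46.1% higher rather than 52.3%), and total counts alone 1194 and 818 (59.3%), so which direction held more genes depended on the fit.

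Genes of pDC identity moved in both directions. Of 30 members, 10 fell, 2 rose and 18 did not pass (12 lower and 2 higher when adjusted over the list alone). Klk1, a kallikrein gene, fell from 960 to 217 CPM (log2FC -2.15), the lectin gene Cd209d from 474 to 68.1 CPM (-2.80). The inhibitory receptor gene Lair1 fell from 1056 ± 83.7 to 444 ± 32.2 CPM (-1.25) and Bst2, which encodes the pDC surface antigen PDCA-1, from 1156 to 743 CPM (-0.64). Dntt, the terminal deoxynucleotidyl transferase gene (chromosome 19, 41029275 to 41059525), rose from 208 ± 35.1 to 496 CPM (log2FC 1.25, SE 0.12, adjusted p = 4.31e-08), and Cox6a2, a cytochrome c oxidase subunit gene, from 376 ± 83.0 to 1004 ± 395 CPM (1.42). Cox6a2 was at 635 and 690 CPM in pDC_TG replicates 1 and 2 and at 1331 and 1359 CPM in replicates 3 and 4. Cox6a2 lies within 200 kb of Itgax, which rose as well. Tcf4, the transcription factor that maintains pDC identity, was at 731 CPM against 718 CPM (log2FC 0.03, adjusted p = 0.962). Siglech, a pDC surface lectin gene, was at 1454 against 2298 CPM (log2FC -0.66, adjusted p = 0.251), and Ccr9, a homing receptor gene, at 943 against 1450 CPM (-0.62, 0.105). In a fit of the pDC libraries alone both passed (adjusted p = 0.000197 and 0.000286), as did falls of Rpgrip1 and Lifr and rises of Ly6d (log2FC 0.55), Atp1b1 (0.53) and Cd7 (0.38), for 14 lower and 5 higher members. The camera test of limma gave adjusted p = 0.0354 for lower pDC identity genes, which became adjusted p = 0.072 with an estimated correlation, 0.052 without pDC_TG replicate 2 and 0.0678 without replicate 3.

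The genes that mark conventional DCs also split by member. Of 18 cDC2 identity genes, 7 rose and 6 fell, with the same numbers adjusted over the list alone. Besides Itgam, the membrane protein gene Tmem176b rose from 38.4 ± 8.68 to 242 ± 49.1 CPM (log2FC 2.65), Tmem176a from 17.6 to 110 CPM (2.65). The lymphotoxin gene Ltb rose from 145 ± 35.9 to 578 ± 22.4 CPM (2.00, adjusted p = 9.83e-11) and the transcription factor gene Irf4 from 146 to 434 CPM (1.58). Cd4 fell from 777 to 470 CPM (-0.73) and Clec10a fell as given. The list's median log2FC was -0.55, while camera called it higher (adjusted p = 0.0249, adjusted p = 0.156 with an estimated correlation), so the median and the test differ in sign. The mean log2 CPM of this list was 5.21 in pDC_TG replicate 4 and 4.82 to 4.85 in the other pDC_TG libraries. Of 19 cDC1 identity genes, 4 rose and 6 fell (4 and 8 adjusted over the list alone), and camera gave adjusted p = 0.0717. They included Cd8a, which encodes the CD8 alpha chain (267 ± 35.7 to 660 ± 161 CPM, log2FC 1.31), the endosomal RNA sensor gene Tlr3 (0.204 to 2.48 CPM, 3.71) and Ifi205 (2.09 to 0.268 CPM, -2.85). Of 12 genes shared by conventional DCs, 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.154 with an estimated correlation, 0.0577 without pDC_TG replicate 2). Itgax, the CD11c gene whose regulatory sequence drives the Cre (chromosome 7, 128129547 to 128150657), rose from 157 ± 50.2 to 408 ± 32.9 CPM (log2FC 1.38, SE 0.17, adjusted p = 3.73e-07). Slamf7 rose from 41.6 to 87.5 CPM (1.07) and Traf1 from 33.9 to 66.7 CPM (0.98), whereas Dpp4 fell from 187 to 145 CPM (-0.37).

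Interferon-stimulated genes, which encode antiviral effectors, rose in pDC_TG: 15 of 24 members were higher and 1 lower (15 and 2 adjusted over the list alone). Camera gave adjusted p = 3.11e-12, which held at 0.00924 with an estimated correlation. The median log2FC was 0.98. The oligoadenylate synthetase genes Oas3 and Oas1a rose from 7.35 ± 2.34 to 48.7 ± 5.77 CPM (log2FC 2.73) and from 12.9 ± 5.53 to 74.9 ± 12.5 CPM (2.54). Xaf1 rose from 16.2 to 50.3 CPM (1.63), Ifit1 from 5.11 to 36.0 CPM (2.82) and Isg15 from 23.9 to 48.7 CPM (1.03), whereas Trim30a fell from 316 to 245 CPM (-0.37). Mx1, an antiviral GTPase gene, was at 5.38 against 5.03 CPM (log2FC 0.10, adjusted p = 0.944). Among 24 genes of nucleic acid sensing and interferon induction, 3 rose and 6 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.0859, 0.0376 without pDC_TG replicate 1). The cytosolic RNA sensor gene Ddx58 (RIG-I) rose from 3.37 ± 1.83 to 55.5 ± 11.3 CPM (log2FC 4.04) and Ifih1 (MDA5) from 16.7 to 34.8 CPM (1.06). Irf5, a transcription factor of the Toll-like receptor pathway, fell from 318 ± 43.3 to 143 ± 30.0 CPM (-1.16, adjusted p = 1.72e-09), as did the nuclease gene Pld4 from 2394 to 1526 CPM (-0.65) and the RNA sensor gene Tlr7 from 384 to 235 CPM (-0.71). Irf7, the transcription factor of interferon induction in pDC, was at 676 against 630 CPM (log2FC 0.10, adjusted p = 0.695) and the DNA sensor gene Tlr9 at 7.07 against 8.84 CPM (-0.32, 0.671).

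Genes of endoplasmic reticulum folding and secretion fell: 13 of 18 members were lower and none higher (14 lower adjusted over the list alone), with camera adjusted p = 1.36e-14 and adjusted p = 0.000374 with an estimated correlation. Xbp1, a regulator of the secretory apparatus (chromosome 11, 5520659 to 5525893), fell from 910 ± 108 to 456 ± 37.1 CPM (adjusted p = 8.36e-09). The disulfide isomerase gene Txndc5 fell from 650 ± 84.1 to 269 ± 31.8 CPM (-1.27), the chaperone gene Hspa5 from 1272 to 808 CPM (-0.66) and Creld2 from 106 to 54.5 CPM (-0.95). Of 20 genes of MHC class I and cross-presentation, 9 were lower and none higher (13 lower adjusted over the list alone, camera adjusted p = 8.55e-08, 0.00924 with an estimated correlation). They included the peptide editor gene Tapbpl (115 to 48.9 CPM, log2FC -1.23), Rab43 (68.0 to 37.4 CPM, -0.86) and the chaperone genes Pdia3 (-0.41) and Calr (-0.32). The list thus holds chaperone genes too, so its fall is not one of MHC class I molecules alone. Of 15 genes of MHC class II presentation, 7 rose and 3 fell (7 and 3 adjusted over the list alone). Camera gave adjusted p = 1.5e-05, with adjusted p = 0.0871 with an estimated correlation. H2-Ob, a subunit of the peptide-loading regulator H2-O, rose from 38.4 ± 5.14 to 191 ± 15.9 CPM (log2FC 2.31, SE 0.11, adjusted p = 2.08e-16). H2-DMb2 rose from 124 to 312 CPM (1.34) and H2-Eb1 from 1789 to 2369 CPM (0.41), whereas the protease gene Ctss fell from 1372 to 1071 CPM (-0.36).

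Transcription factor genes of DCs included 7 rises and 3 falls among 31 members (7 and 4 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.154 with an estimated correlation). Prdm1, which encodes the repressor BLIMP-1 (chromosome 10, 44437177 to 44528501), rose from 6.18 ± 2.15 to 63.9 ± 11.8 CPM (log2FC 3.37). Spi1, which encodes PU.1, rose from 96.2 ± 11.2 to 202 ± 18.6 CPM (1.07, adjusted p = 1.28e-11), Bcl6 from 17.8 to 37.4 CPM (1.07) and Irf2 from 57.3 to 107 CPM (0.90). Apoptosis regulators included 7 rises and 1 fall among 25 members (8 and 1 adjusted over the list alone, camera adjusted p = 0.0132, which held at 0.0302 with an estimated correlation). The survival gene Bcl2 rose from 7.16 ± 2.07 to 22.6 ± 0.340 CPM (log2FC 1.65). The death-promoting genes Bmf (1.25) and Bid (0.63) rose. The survival gene Bcl2l1 fell from 11.7 to 7.14 CPM (-0.71). Mcl1, a further survival gene, was at 481 against 455 CPM (log2FC 0.08, adjusted p = 0.656).

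Cell cycle genes included 17 rises and no fall among 25 members (21 rises adjusted over the list alone, camera adjusted p = 2.64e-11, adjusted p = 0.0784 with an estimated correlation). The count was 8 without pDC_TG replicate 4, 9 in a fit of the pDC libraries alone and 10 with WT replicates 1 to 4 alone. The summed level of the list was 424 to 542 CPM in pDC_TG replicates 1 to 3, 688 CPM in replicate 4 and 297 to 373 CPM in pDC_WT. Mcm7, a DNA replication helicase gene, rose from 30.4 ± 2.25 to 54.2 ± 10.3 CPM (log2FC 0.83), Ube2c from 0.818 to 6.63 ± 5.50 CPM (3.01), Birc5 from 0.872 to 6.12 ± 6.02 CPM (2.79) and the cyclin gene Ccna2 from 2.35 to 13.2 ± 12.3 CPM (2.48). The proliferation marker Mki67 was at 1.61 against 1.24 CPM (0.37, adjusted p = 0.860). pDC_TG replicate 4 also held neutrophil transcripts: its summed neutrophil marker level was 181 CPM, against 1.77 to 6.82 CPM in the other pDC_TG libraries and 2.03 to 5.43 CPM in pDC_WT. Of 9 neutrophil markers, 5 were called higher (6 adjusted over the list alone, camera adjusted p = 0.340), including S100a8, Ngp, Ltf and Lcn2, and without that library the count was 0.

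Among 22 migration and adhesion receptor genes, 8 rose and 5 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.0686, 0.0424 without pDC_TG replicate 3). Ccr7, the receptor that guides DCs to lymph nodes, rose from 57.7 ± 10.1 to 178 ± 41.5 CPM (log2FC 1.62) and the chemokine receptor gene Ccr1 from 21.2 to 173 CPM (3.03), whereas Cxcr3 fell from 212 ± 42.0 to 71.8 ± 14.7 CPM (-1.57). Among 22 costimulation and priming genes, 6 rose and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0686, 0.0432 without pDC_TG replicate 3, 0.0448 without replicate 1 and 0.0463 without replicate 2). Cd80, a ligand of CD28, rose from 1.22 to 8.02 CPM (log2FC 2.70) and Tnfsf9 from 13.2 to 56.5 CPM (2.09), and Cd40 fell from 11.3 to 1.72 CPM (-2.69). Of 23 C-type lectin and phagocytic receptor genes, 5 rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.191). The inhibitory receptor gene Clec12a rose from 536 to 1213 CPM (1.18) and the Fc receptor gene Fcgr2b from 17.3 to 28.1 CPM (0.70). Fcgr2b lost its call with WT replicates 1 to 4 alone (log2FC 0.55, adjusted p = 0.0688) and against a 1.5-fold change (0.684). The number of falls in this list was 2 without pDC_TG replicate 1 or 3 or without pDC_WT replicate 6 or 7. Of 18 dissociation and immediate early genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.144). There were rises of Ier3 (3.10 to 26.4 CPM, 3.09), Atf3 (21.7 to 83.7 CPM, 1.95) and Egr1 (61.2 to 113 CPM, 0.89) and a fall of Btg2 (1227 to 827 CPM, -0.57). Without pDC_TG replicate 3, this list held 3 rises and 1 fall.

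Some members of the lymphocyte marker lists rose. Sdc1, which encodes the plasma cell antigen CD138 (chromosome 12, 8771323 to 8793715), rose from 51.2 ± 9.81 to 1108 ± 160 CPM (log2FC 4.44, SE 0.31, adjusted p = 1.6e-11). Mzb1, a further plasma cell gene that shares 57.2% of its exonic bases with another gene, fell from 197 ± 57.2 to 40.1 ± 23.5 CPM (-2.30, adjusted p = 0.000885, 0.124 in the DESeq2 Wald test) and Jchain was at 47.2 against 23.1 CPM (1.03, adjusted p = 0.595, 0.0152 in limma-voom). Of 3 plasma cell markers, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.279, and 5.34e-06 for higher genes in a fit of the pDC libraries alone). Of 10 B cell markers, 3 rose and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.154 with an estimated correlation). They were Cd22, an inhibitory receptor (2.18 to 42.1 CPM, log2FC 4.25), Bank1 (1.03 to 17.9 CPM, 4.12) and Fcer2a (1.15 to 7.21 CPM, 2.64, adjusted p = 0.00274, and 0.0734 with WT replicates 5 to 8 alone). Cd79a, a subunit gene of the B cell receptor complex, was at 3.24 against 5.51 CPM. The summed level of the B cell list, which its most abundant members set, was not higher (320 to 389 CPM in pDC_TG, 322 to 415 CPM in pDC_WT). Of 10 T cell markers, 3 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0169, adjusted p = 0.105 with an estimated correlation). They were the transcription factor gene Tcf7 (0.721 to 15.3 CPM, 4.40), the kinase gene Lck (4.12 to 66.4 CPM, 4.01) and Cd5 (4.58 to 21.3 CPM, 2.22). Cd3e, a subunit gene of the T cell receptor complex, was at 0.50 against 0.36 CPM. T cells in the sort were not tested as an origin of these transcripts. Without pDC_TG replicate 4 the counts in both lists were still 3, and camera gave adjusted p = 0.0523 for the T cell list. In a fit of the pDC libraries alone it gave 0.11 for the B cell list.

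The remaining marker lists held few calls. Of 7 NK cell markers, only Ccl5 was higher (0.183 to 0.897 CPM, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.269), and it was not called in a fit of the pDC libraries alone (adjusted p = 0.142). Of 16 monocyte and macrophage markers, Lyz1, Chil3 and Ms4a4c were higher and C1qb and C1qc lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.426), and without pDC_TG replicate 4 none was higher and 3 were lower. Ms4a4c (log2FC 0.96, adjusted p = 0.0127) also lost its call without replicate 3 (0.121), and C1qc in a fit of the pDC libraries alone (0.0678). Neither the 5 erythroid and platelet markers (camera adjusted p = 0.949) nor the 5 sex-linked genes (0.955) held a call in the edgeR test or adjusted over the list alone.

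**Figure D2:**
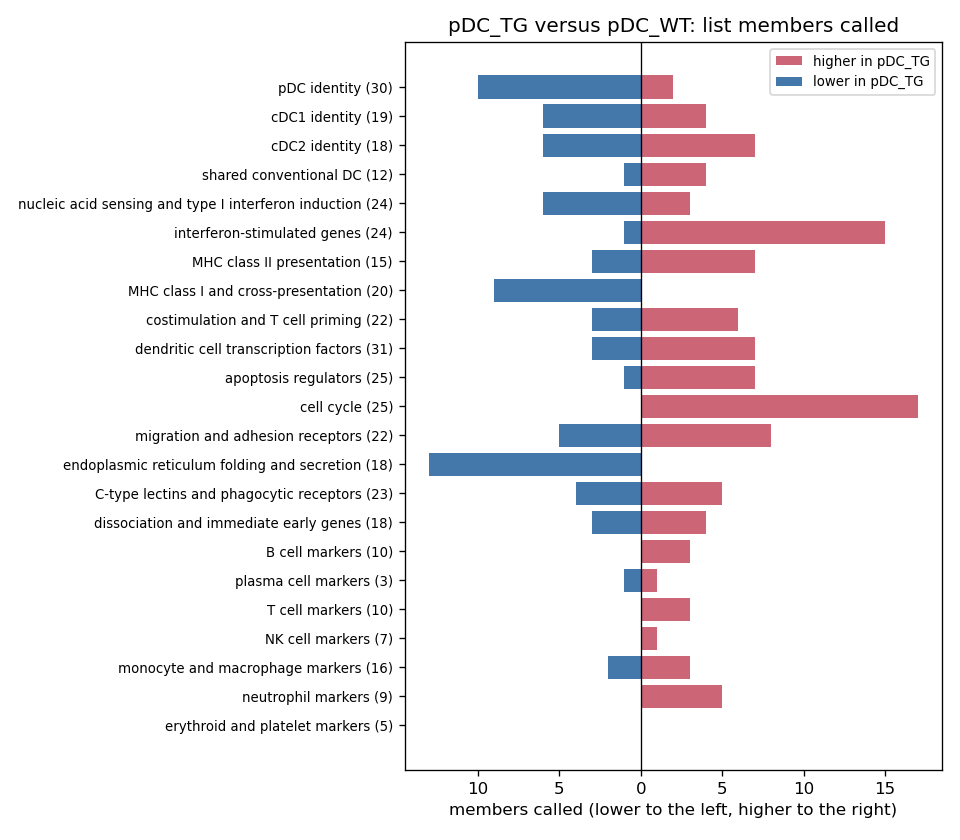
Number of list members called higher or lower in pDC_TG than in pDC_WT (horizontal axis, genes; edgeR, adjusted over all genes tested) for 23 gene lists, with the number of tested members in parentheses. Endoplasmic reticulum folding (13 of 18) and MHC class I and cross-presentation genes (9 of 20) hold lower calls alone. Interferon-stimulated (15 of 24) and cell cycle genes (17 of 25, or 8 without pDC_TG replicate 4) hold mostly or wholly higher calls.

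Genes that set the WT populations apart were then followed in pDC_TG, with odd-numbered pDC_WT libraries defining the signatures and even-numbered ones as control. Of 609 tested pDC signature genes, 130 were lower and 61 higher in pDC_TG, so that 31.4% were called against 9.78% of other genes. The cDC2 signature held 60 higher genes and 1 lower among 181 (33.7% against 10.6%), the cDC1 signature 10 higher and 13 lower among 124 (18.5% against 10.8%) and the signature shared by both conventional DCs 67 higher and 12 lower among 493 (16.0% against 10.7%). Most cDC1 and cDC2 signature genes were too low in pDC to be tested (124 tested of 292 and 181 of 427, with 493 of 937 for the shared signature), and a filter that also reads pDC_TG favours genes that rose there. Among genes with at least 1 CPM in the defining pDC_WT libraries, a limit set after the data were seen that does not depend on pDC_TG, the cDC2 signature held 46 higher and 1 lower of 116 tested (40.5% against 11.0%), the cDC1 signature 8 and 13 of 97 and the shared signature 50 and 12 of 312. Higher cDC1 signature genes numbered 3 without pDC_TG replicate 2 and 5 without replicate 3. The share of cDC1 signature genes called was then 8.82% against 7.79% of other genes, and 10.4% against 7.98%, so little of its excess remained. Lower cDC2 signature genes numbered 3 without replicate 1 and 2 without replicate 4, and lower shared signature genes 5 without replicate 1 or 3 and 7 without replicate 2. Odd and even numbers also part female from male mice; with pDC_WT replicates 1 to 4 defining and 5 to 8 as control, a split chosen after the data were seen, the pDC signature held 134 lower and 69 higher genes and the cDC2 signature 66 higher and 2 lower.

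Across 10759 genes, which are not independent replicates, the change in pDC_TG correlated with the difference of cDC2_WT from pDC_WT at r = 0.298 and with that of cDC1_WT at r = 0.136, on separate controls. In 100 simulations of unchanged groups the highest r was 0.0355 and 0.0342. The observed covariances of 0.446 and 0.225 compare with simulated means of 6e-04 and 8e-04. The simulated genes varied independently, whereas genes of real libraries vary together, so the simulations understate the spread of r by chance. Without pDC_TG replicate 4 the correlations were 0.252 and 0.0990. Of the 1016 genes higher in pDC_TG, 689 were also higher in cDC2_WT than in pDC_WT and 536 higher in cDC1_WT, where independent lists would share 292 and 311. Of the 927 lower genes, 562 and 452 were lower there too, against 263 and 281. These overlaps use the same pDC_WT libraries on both sides, which adds to them by construction. The counts for independent lists are therefore not those of unchanged groups.

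**Figure D3:**
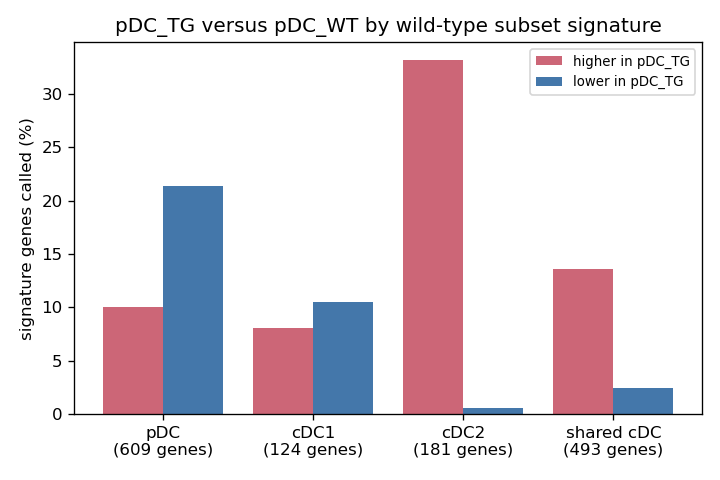
Percent of tested signature genes (vertical axis) called higher or lower in pDC_TG than in even-numbered pDC_WT, for the pDC, cDC1, cDC2 and shared conventional DC signatures. The pDC signature holds more lower (130 of 609) than higher genes, and the cDC2 signature 60 higher and 1 lower of 181.

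The WT populations were compared to give the reference for these changes. In cDC1_WT against pDC_WT, the chemokine receptor gene Xcr1, which marks cDC1, was at 1154 ± 131 against 1.96 ± 0.975 CPM (log2FC 9.21, SE 0.24, adjusted p = 7.51e-21). The lysosomal hydrolase genes Naaa and Ppt1 were at 2777 ± 238 against 21.2 ± 4.95 CPM (7.03) and 6737 ± 679 against 238 ± 20.7 CPM (4.83), and Id2, an inhibitor of the pDC program, at 1602 ± 233 against 6.13 ± 0.928 CPM (8.03). Fam149a (chromosome 8, 45336717 to 45382291) was at 113 ± 11.7 CPM in cDC1_WT and without a count in pDC_WT, at least 7748-fold higher. Likewise without a count there, Mab21l3 was at least 6603-fold, Dkk3 6231-fold and Itga8 5091-fold higher, while Ocstamp was at 162 against 0.00459 CPM. Dntt was without a count in cDC1_WT, at least 13150-fold lower than in pDC_WT, and the kinase gene Pnck at least 4838-fold lower. Tlr7 was at 0.0108 against 384 ± 63.6 CPM, Mctp2 at 0.0165 against 409 CPM and the cadherin gene Cdh1 at 0.0114 against 271 CPM.

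All 30 pDC identity genes were lower in cDC1_WT (camera adjusted p = 4.08e-56), such as Smim5 (log2FC -13.76), Lair1 (-6.40) and Bst2 (-4.92). All 19 cDC1 identity genes were higher (8.78e-28), as were all 12 shared conventional DC genes (2.42e-16), such as Kit (3.49) and Slamf7 (3.00), with the same numbers adjusted over the list alone. Of 18 cDC2 identity genes, 5 were higher and 11 lower, also when adjusted over the list alone (4.67e-05, adjusted p = 0.0191 with an estimated correlation), among them Clec10a (-11.85), Cd4 (-6.73) and Cd209a (-6.52). All 25 cell cycle genes were higher, also when adjusted over the list alone (3.22e-12, adjusted p = 0.0522 with an estimated correlation), as were 19 of 22 costimulation genes, with 1 lower in both counts (4.37e-09), and 19 of 25 apoptosis regulators (19 higher and 2 lower adjusted over the list alone, 2.71e-08). The counts were 4030 higher and 3982 lower genes. Scaling by total counts alone gave 3072 higher and 5327 lower, or 36.6% higher rather than 50.3%, since it moved the median log2FC by -0.25, so directions here are relative to TMM scaling.

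In cDC2_WT against pDC_WT, Tmem176b was at 1195 ± 132 against 38.4 ± 8.68 CPM (log2FC 4.96) and Tmem176a at 752 ± 115 against 17.6 ± 4.10 CPM (5.42). The inhibitory lectin gene Clec4a4 was at 218 ± 17.8 against 0.0837 CPM (11.44), Id2 at 335 ± 35.9 against 6.13 CPM (5.77) and Kit, a growth factor receptor, at 636 ± 60.0 against 32.3 CPM (4.30). The nonclassical MHC gene H2-M2 (82.2 ± 18.9 CPM) was at least 5644-fold higher, Adgrl3 5394-fold, the pyrin gene Mefv 4659-fold and LOC100038947, for which no position was found, 4041-fold. Sirpb1a was higher by a log2FC of 13.03. The collagen chaperone gene Serpinh1 was at least 4722-fold and Klk1b27 at least 4048-fold lower. Klk1 was at 0.0840 against 960 ± 197 CPM (-13.41), Dntt at 0.00511 against 208 CPM and the glutamate receptor gene Grm8 at 0.00469 against 90.1 CPM. All 30 pDC identity genes were lower (camera adjusted p = 5.44e-52), such as Ly6c2 (-10.98) and Bst2 (-5.15), also when adjusted over the list alone. Of 18 cDC2 identity genes, 11 were higher and 3 lower (12 and 3 adjusted over the list alone, 0.00129, adjusted p = 0.0836 with an estimated correlation). Of 19 cDC1 identity genes, 8 were higher and 7 lower in both counts (0.385), such as Batf3, a transcription factor (9.31), Clec9a (-3.28) and Cd8a (-6.62). Of the 12 shared genes, 11 were higher, Traf1 (3.40) among them, in both counts (4.86e-16). MHC class II genes were higher in 13 of 15 and lower in 1 (8.51e-16, 0.000998 with an estimated correlation), and all 25 cell cycle genes were higher (2.24e-12, 0.0479), with the same numbers adjusted over the list alone. Interferon-stimulated genes were higher in 13 of 24 and lower in 7, in both counts (camera adjusted p = 0.385, 0.775 with an estimated correlation). Endoplasmic reticulum folding genes were lower in 12 of 18 and higher in 4, in both counts (2.49e-05, 0.0235). The counts were 3787 higher and 3728 lower genes, and with total counts alone 3108 and 4542, with the median log2FC moved by -0.15.

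In cDC1_WT against cDC2_WT, Gcsam, a signalling gene of germinal centre cells, was at 467 ± 38.7 against 0.0823 CPM (log2FC 12.45), the trafficking gene Rab7b at 481 ± 42.6 against 0.709 CPM (9.41), Ppt1 at 6737 against 214 ± 21.6 CPM (4.98) and Naaa at 2777 against 67.6 ± 14.6 CPM (5.36). Gramd2 was at least 1330-fold and the receptor gene Igf2r at least 1079-fold higher, and Dkk3 (90.8 against 0.0165 CPM) and P3h2 (log2FC 11.06) were also among the largest rises. Tlr7 was at 0.0108 against 126 ± 19.7 CPM, the flagellin receptor gene Tlr5 at least 2096-fold lower, and Dscam at 0.0109 against 57.5 CPM, LOC100038947 at 0.0136 against 58.9 CPM and Scn3a at 0.00544 against 30.7 CPM. All 19 cDC1 identity genes were higher (camera adjusted p = 2.43e-45), and 17 of 18 cDC2 identity genes lower with 1 higher (5.46e-27), such as Cd4 (-5.11), Tmem176b (-3.97) and Ltb (-3.71), with the same numbers adjusted over the list alone. Of 12 shared genes, 2 were higher and 3 lower (3 and 3 adjusted over the list alone, 0.519), such as Btla (3.01), Id2 (2.26) and Itgax (-0.97). Of 30 pDC identity genes, 9 were higher and 12 lower (10 and 13 adjusted over the list alone, 0.0183, and 0.0526 with the replicate number as a block), such as Lair1 (-4.02) and Cd7 (-7.54). Endoplasmic reticulum folding genes were higher in 15 of 18 in both counts (5.66e-10, 0.00209 with an estimated correlation). MHC class I and cross-presentation genes were higher in 13 of 20, with 3 lower in both counts (4.92e-06, 0.0191). Interferon-stimulated genes were lower in 17 of 24 with 2 higher (3 higher adjusted over the list alone, 3.02e-06, adjusted p = 0.0884 with an estimated correlation). The counts were 3003 higher and 3082 lower genes, and with total counts alone 2524 and 3633.

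Against cDC1_WT, pDC_TG held Dntt at 496 CPM (at least 31370-fold higher), Lrrc15 at 133 ± 21.4 CPM (8441-fold), Gpr25 (6246-fold) and Pnck (4802-fold), with no count of these genes in cDC1_WT, and Tlr7 at 235 ± 32.8 against 0.0108 CPM. The receptor gene Tlr11, at 467 ± 61.5 CPM in cDC1_WT, was at least 17730-fold lower in pDC_TG, the Wnt receptor gene Fzd1 8528-fold, Ocstamp 6156-fold and Snx22 5756-fold, and Apol7c was at 0.0269 against 1440 ± 280 CPM. All 30 pDC identity genes were higher in pDC_TG (camera adjusted p = 8.63e-60), 18 of 19 cDC1 identity genes lower (1.14e-25), 11 of 12 shared conventional DC genes lower (2.73e-11) and 14 of 18 cDC2 identity genes higher with 2 lower (2.19e-08), with the same numbers adjusted over the list alone. Interferon-stimulated genes were higher in 19 of 24 and lower in 1, in both counts (1.44e-07, 0.0399 with an estimated correlation). The counts were 3561 higher and 3494 lower genes, and with total counts alone 4973 and 2507, or 66.5% higher rather than 50.5%, with the median log2FC moved by 0.29.

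Against cDC2_WT, pDC_TG held Dntt at 496 against 0.00511 CPM, the thromboxane receptor gene Tbxa2r at 204 ± 19.1 against 0.0210 CPM, and Lrrc15 at 133 against 0.0156 CPM, while Fbxl13, without a count in cDC2_WT, was at least 2043-fold higher. The peptidase gene Ace was at least 3163-fold lower, the interleukin 1 antagonist gene Il1rn 2931-fold, Sirpb1b 2167-fold and the transcription factor gene Tbx21 2164-fold, and Adgre4 was at 0.00832 against 273 ± 69.5 CPM. All 30 pDC identity genes were higher in pDC_TG (camera adjusted p = 2.59e-63), 11 of 12 shared conventional DC genes lower (1.02e-12) and 12 of 18 cDC2 identity genes lower with 4 higher (0.00925, adjusted p = 0.108 with an estimated correlation), with the same numbers adjusted over the list alone. Of 19 cDC1 identity genes, 5 were higher and 9 lower (6 and 10 adjusted over the list alone, 0.104). MHC class II genes were lower in 14 of 15 with 1 higher (9e-11, 0.00775) and costimulation genes in 18 of 22 with 1 higher (5.56e-10, 9.06e-05 with an estimated correlation), in both counts. Interferon-stimulated genes were higher in 10 of 24 and lower in 1, in both counts. Camera did not call that list (adjusted p = 0.0771, 0.484 with an estimated correlation), though it did in a fit of these 2 groups alone (0.029). The counts were 3200 higher and 3141 lower genes, and with total counts alone 4267 and 2487, or 63.2% higher rather than 50.5%, with the median log2FC moved by 0.20.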

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

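The tests of the interferon-stimulated genes without pDC_TG replicate 4 and against a rise of like size, against a common change of all members, of the cell cycle genes and their level without that replicate, and of a cDC2 share in pDC_TG were chosen only after the result was seen.

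Single libraries stood apart from their group in 6 of 135 tests, where 6.75 are expected by chance, since chance singles out about 1 in 20 groups. The mean log2 CPM of T cell markers was 0.911 in pDC_WT replicate 5 and -0.0595 to 0.321 in the other pDC_WT libraries. In pDC_TG, cDC2 identity genes were at 5.21 in replicate 4 (others 4.82 to 4.85), interferon-stimulated genes at 5.74 in replicate 2 (others 5.97 to 6.01) and Itgam at 19.1 CPM in replicate 3 (others 35.5 to 36.5). Neutrophil markers were at 1.33 in cDC1_WT replicate 4 (others -3.05 to -1.82) and migration and adhesion receptors at 5.71 in cDC2_WT replicate 1 (others 5.91 to 6.04).

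Of 11968 genes, 1 had a change in pDC_TG that differed between the sexes: for Slc22a23 the male minus female log2 change was 9.53 (adjusted p = 7.16e-05). It was at 0 CPM in pDC_TG of female mice, 3.91 CPM in pDC_TG of male mice and 19.8 and 22.4 CPM in pDC_WT of female and male mice, so the fitted value depends on how the 0 is handled.

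To see what arbitrary groups give, the libraries of each comparison were regrouped in 100 drawn splits, and in each comparison the number of splits that called as many genes as the real one was 1, the real split itself. The real and highest other counts were 1782 and 1 for pDC_TG versus pDC_WT, 7108 and 3476 for cDC1_WT versus pDC_WT, 6902 and 0 for cDC2_WT versus pDC_WT, 5808 and 3385 for cDC1_WT versus cDC2_WT, 6408 and 0 for pDC_TG versus cDC1_WT and 6168 and 3 for pDC_TG versus cDC2_WT. Among splits that part every pair of same-numbered WT libraries, the highest other counts were 3678 for cDC1_WT versus pDC_WT, 3486 for cDC2_WT versus pDC_WT and 3151 for cDC1_WT versus cDC2_WT, with 4, 7 and 7 other splits over 100 genes. The counts above 3000 came from splits that kept 14 of 16 libraries on their real side. This argues against an arbitrary division of the libraries as the source of the calls. It cannot address a difference in handling that follows the groups. Mixed splits also carry the real difference as spread within groups, which lowers their counts.

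Interferon-stimulated genes were higher in pDC_TG, and the neutrophil transcripts in pDC_TG replicate 4 could have added to this. Without that library 15 members were still called higher, which argues against that explanation. With a length slope per library as a covariate 15 were called too. This slope describes how a library's log2 CPM, less the mean of all libraries, varied with the log2 exonic length of genes. The slope was taken from the same counts. That fit argues against a length-related difference in RNA or library quality between libraries. For 4 members the upper 2 SE bound of the change lay below 0.5 log2. That count fell between the bounds set for and against a rise of like size, so it decides nothing. The squared differences of the 24 members from their weighted mean were 26.8 times what their SE allow. This argues against a common change of all members, though the test was chosen after calls in both directions were seen. Whether interferon signalling or another input to these genes lies behind the rise is not decided by these data.

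Cell cycle genes were higher in pDC_TG by camera (adjusted p = 2.64e-11), though not with an estimated correlation (adjusted p = 0.0784), and the rise may come in part from pDC_TG replicate 4. Without that library 8 members were called rather than 17, against 20, 18 and 15 without replicate 1, 2 and 3. The 8 lies under the bound set for that library as a cause. The mean log2 CPM of the list was 1.40 (SE 0.52) above pDC_WT with all pDC_TG libraries and 1.01 (SE 0.44) without replicate 4. Without it the ranges overlapped (1.815 to 3.163, against 0.684 to 2.128 in pDC_WT). With so few libraries this difference does not decide whether that replicate is the whole of the rise. The summed level, which the most abundant members set, was 424 to 542 CPM in pDC_TG replicates 1 to 3 and 297 to 373 CPM in pDC_WT. A rise of that sum was thus present without replicate 4. With each library's length slope as a covariate 14 were called, just reaching the bound set against a length-related difference in library quality. Since the count did not go past that bound, such a difference was left open. A mixture of dividing cells in the other pDC_TG libraries was not tested.

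The rise of Itgam and Itgax in pDC_TG might come from extra transgene copies or from cDC2 in the sort. The 9 other tested genes within 200 kb of Itgax had a median log2FC of 0.062 (SE of the median 0.292), with 2 higher and 0 lower, which leaves transgene copies open. The 2 were Itgad (log2FC 2.01) and Cox6a2 (1.42), the next tested genes after Itgax, and they are named here after their values were seen. Itgad shares 19.7% of its exonic bases with other genes, Cox6a2 among them, so the counts of the 2 may not be independent. Over 82 other cDC2 genes, the median implied cDC2 share was at most 1.63% of the share that Itgam implies in any pDC_TG library, which argues against cDC2 cells as the source of Itgam. The transgene itself was not analysed here.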

How the results depend on the processing

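The signature split by replicates 1 to 4 and 5 to 8 and the 1 CPM floors were chosen only after the result was seen. So were the sex and length slope covariates. The bounds for the length slope in the gene lists were written before that test was run. Where no reason is given, the cause was not tested.

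Tested against a 1.5-fold change, the numbers of higher and lower genes were 337 and 194 for pDC_TG versus pDC_WT, 2365 and 2412 for cDC1_WT versus pDC_WT, 2322 and 2068 for cDC2_WT versus pDC_WT, 1193 and 1553 for cDC1_WT versus cDC2_WT, 2256 and 2103 for pDC_TG versus cDC1_WT and 1700 and 1912 for pDC_TG versus cDC2_WT. They are smaller by construction, since the test asks for more. With WT replicates 1 to 4 only, cDC1_WT versus cDC2_WT held 1872 higher and 2049 lower genes.

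The replicate number as a block pairs the WT groups and has no support for pDC_TG. With it, the camera adjusted p in pDC_TG versus pDC_WT was 0.0696 for pDC identity, 0.131 for cDC2 identity, 0.023 for nucleic acid sensing and 0.0696 for DC transcription factors. The block changed no other call of a list in that comparison.

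With an estimated correlation, camera gave adjusted p = 0.072 for pDC identity, 0.156 for cDC2 identity, 0.154 for shared conventional DC genes and for DC transcription factors, 0.0871 for MHC class II and 0.0784 for the cell cycle in pDC_TG versus pDC_WT. The rotation test fry called lists that camera did not, with adjusted p = 0.000122 for cDC1 identity, 0.0172 for nucleic acid sensing, 0.000864 for costimulation, 0.000586 for migration, 0.0271 for C-type lectins, 0.0213 for immediate early genes, 0.0213 for plasma cell markers and 0.0246 for NK cell markers. It tests each list against no change, not against other genes.

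Leaving out 1 pDC_TG library gave camera adjusted p from 0.0448 to 0.0678 for pDC identity, 0.00214 to 0.0577 for shared conventional DC genes, 0.0376 to 0.184 for nucleic acid sensing, 0.0432 to 0.203 for costimulation and 0.0424 to 0.102 for migration. Without pDC_TG replicate 4, which holds most of the neutrophil transcripts, the log2FC of Chil3 was 0, since no count of it remained in either group, and that of Ltf was -2.71 (adjusted p = 0.581), since no count of it remained in pDC_TG. Over the other libraries left out, the log2FC of Chil3 in pDC_TG versus pDC_WT was at most 9.69 and that of Ltf in pDC_TG versus pDC_WT at most 9.38. Chil3 had no count in pDC_WT and Ltf none in pDC_TG replicates 1 to 3, so both fitted values depend on how the 0 is handled.

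For the signatures in pDC_TG, lists defined by a 2-fold difference held 92 higher and 228 lower pDC genes, 16 and 46 cDC1 genes, 122 and 15 cDC2 genes and 125 and 35 shared genes, larger by construction since the lists are longer. With unsplit controls 21 cDC1 genes and 3 cDC2 genes were lower. With pDC_WT replicates 1 to 4 defining and 5 to 8 as control, 2 cDC2 genes were lower. Leaving out 1 library gave 3 to 8 higher cDC1 genes, 1 to 3 lower cDC2 genes and 5 to 10 lower shared genes.

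The correlation of the pDC_TG change with the cDC1 difference was 0.174 with unsplit controls, where shared controls add to it by construction, and 0.0990 to 0.152 with 1 library left out. That with the cDC2 difference was 0.325 with odd and even controls swapped, 0.35 with unsplit controls and 0.252 to 0.309 with 1 library left out.

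Of 107 named genes in pDC_TG versus pDC_WT, 76 kept their state, called or not called, under every setting and 31 changed under at least 1. The 76 include genes that were never called, such as the sex-linked genes. All named genes of the other comparisons kept their state. The numbers of higher and lower genes in pDC_TG versus pDC_WT were 934 and 884 at 1 CPM or more. They were 1011 and 924 with sex as a covariate and 1040 and 1063 with the length slope.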
